A study of Mus musculus with 9 samples.

How the data were processed

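Messenger RNA was measured in mouse embryonic fibroblasts (MEFs), cells grown from mouse embryos, of 1 wild-type (WT) line and 1 line that the labels call mutator. Per the labels' protocols, wells of a 6-well plate were seeded from each line, 5 wells per line were plated as technical replicates, and cells were harvested after 48 h without treatment. Poly(A)-selected, strand-specific libraries were made from 1 µg of RNA and sequenced as 150 bp paired-end reads. The comparison used 4 WT and 5 mutator libraries. There was 1 cell line per genotype, so the p-values measure the spread between wells of those lines, which is technical, and a difference of genotype and any other difference between the lines share the same contrast.

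The deposited file is a table of raw counts per gene that the authors made from aligned reads. Per the submitters' processing notes, the tools were STAR 2.4.2a and HTSeq and the genome build was mm10. The HTSeq version, the gene annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here. The table has 29915 rows named by gene. Of these, 7050 have a name in the form of a sequence accession and are called rows named by accession below. They were picked by that form alone and include the older gene symbol AI314180. No row without a gene name was found. Library columns were matched to samples by the sample descriptions, and 5 further columns that match no sample here were not used. With the strand setting not given, reads of a gene and of an overlapping antisense gene could not be told apart, and reads over overlapping genes or near-identical copies may be missing or split.

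The depth per library, as the sum of the counts, was 26341230 to 36238653 for WT and 32045662 to 49511365 for mutator. The 10 most abundant genes took 4.53 to 5.14% of the counts in WT and 4.39 to 4.48% in mutator. In all 16 pairs of replicates the counts differed by more than sampling noise over genes with at least 20 counts in the pair (chi-square per degree of freedom 2.49 to 12.4), so each library was counted as its own sample. For a gene with no counts in a group, the floor was 3 counts over the group's summed libraries, and folds against it are lower bounds. With 1 to 3 counts in a group, the ratio of summed counts is given with its exact Clopper-Pearson interval. These floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

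Genes were kept by edgeR's filterByExpr by group, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, mutator against WT, group the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are log2 of mutator over WT, with a standard error (SE) taken as the size of the log2 fold change divided by the square root of F. CPM values are the unit edgeR gives by that name, with TMM-scaled library sizes, computed here from the deposited counts. A second count asked in addition for a fitted change of at least 2-fold. The 36 gene lists were fixed before the data were examined. They cover the proteasome 20S core, its 19S regulator, its assembly chaperones, the immunoproteasome with alternative activators, and proteasome transcription with ubiquitin supply. Others cover mitochondrial genes, metabolism, stress responses, proliferation, matrix, position and imprinted genes, X- and Y-linked transcripts and markers of other cell types. Of 786 list entries, 773 were found in the table, 10 of them under an older symbol. Lists with at least 3 tested genes were tested with limma 3.58.1: camera with a preset inter-gene correlation of 0.01 on log2 CPM (prior count 2) was the main test, which compares a list with all other genes. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, were alternatives. The estimated correlation comes from deviations between wells within each line. Adjustment was over the 32 lists tested.

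The genes named in the text follow a rule set before the data were examined. It takes the 6 highest and 6 lowest fold changes among genes past the threshold with a mean of at least 10 CPM, no overlap between the groups' libraries and a gene symbol that is not a provisional one. It takes the 3 largest absolute changes past the threshold in each list among genes with a mean of at least 1 CPM. It always takes Psmd10, Psmd5, Psmd9, Psmb5, Psmd11, Psmb8, Nfe2l1, Atf4, Polg, Nnt, Xist and Ddx3y. Some genes that meet these criteria are not reported. Members of small groups of exceptions within a list, the HoxB and imprinted genes beyond the 3 per list, and the cytokine genes among the closing observations were chosen after their values were seen.

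Chromosomes and positions come from the RefSeq annotation of GRCm38, the assembly also called mm10; 22336 rows matched, 19389 by symbol and 2947 by a unique older symbol. Chromosome medians of the log2 fold change were set against 10000 permutations of the genes' values over all chromosomes, taking the largest deviation among chromosomes in each. GC content and transcript length were taken from GENCODE transcripts of the same build for 12460 of the 13345 genes tested (93.4%). Their trend was fitted with natural splines of 4 degrees of freedom each. The 33 core and regulator genes were set against 10000 random lists of the same size drawn from 50 classes of mean expression.

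Alternatives set before the data were examined were DESeq2 size factors, upper quartile scaling, library sizes without mitochondrial genes, no filter, a filter of at least 10 CPM in at least 4 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, leaving out each library in turn, a glmTreat test against a fold of 1.5, and the 2 other list tests. Added after the data were seen were fold changes relative to the chromosome median, a correction for GC content and length, both together (added once the GC and length correction alone had been seen), a chromosome-centred list test with estimated correlation, and library sizes without rows named by accession and without the mitochondrial rows Cytb and mt-Nd4.

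The tests were tried on simulated counts with the real means, dispersions and library sizes for WT against mutator, with 50 genes changed at each fold. On 13180 genes, edgeR recovered 15 of 50 genes changed by 1.1-fold, 38 of 50 at 1.25-fold, 42 of 50 at 1.5-fold and 45 of 50 at 2-fold, and 11 of 151 calls were false. A simulated chromosome 3 shift of -0.7 came out as a median of -0.67, with no other chromosome median beyond 0.056 in size. Camera gave an adjusted p of 0.000664 for a lowered 20S core list and called 0 of 31 lists where no list had an effect. The lowered list was given a narrower spread than the other genes. Genes were simulated independently of each other, whereas the estimated correlation was 0.258 for the real core list. The simulation therefore cannot show how often camera calls lists of correlated genes.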

Results

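Strand-specific RNA sequencing of poly(A)-selected RNA was used to compare mouse embryonic fibroblasts (MEFs) of 1 wild-type (WT) line with MEFs of 1 mutator line. The series states that the aim was the expression of proteasome subunits. The proteasome is the protease that degrades ubiquitin-tagged proteins; it consists of a 20S core, which holds the proteolytic sites, and a 19S regulator, which binds and unfolds substrates. The labels give the genotype only as mutator. In mouse work the name is used for animals whose mitochondrial DNA polymerase, encoded by Polg, lacks proofreading, so that mitochondrial DNA mutations accumulate. The allele cannot be read from gene counts, and Polg RNA was 95.9 ± 2.49 CPM in WT (SD, n = 4) and 102 ± 1.89 CPM in mutator (SD, n = 5). Its log2 fold change was 0.09 ± 0.026 (SE); it did not pass relative to its chromosome median (0.05), and was -0.04 after a correction for GC content and transcript length. There were 4 WT libraries with 26341230 to 36238653 counts and 5 mutator libraries with 32045662 to 49511365 counts, from wells of the same plate format harvested at 48 h. The wells are technical replicates, so each p-value measures well-to-well spread within 1 line per genotype.

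The lines differed across most of the expressed genome. The first principal component held 94.1% of the variance and separated WT from mutator. Of 13345 genes tested, 5438 were higher and 5227 lower in mutator (79.9% past the threshold, edgeR quasi-likelihood test), and 1509 were higher and 871 lower by at least 2-fold. In 9597 genes the libraries of the groups did not overlap, where chance alone gives 1.59%. The median log2 fold change of all genes was 0.01. The count of genes with a change of at least 2-fold depended on the filter: 610 were higher and 321 lower under a filter of at least 10 CPM in 4 libraries.

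The genes with the largest fold changes at a mean of at least 10 CPM included genes of transcription factors, of adhesion proteins and of a collagen. Tbx4 and Pitx1, transcription factors of hindlimb identity, were high in mutator and near or at 0 in WT. Pitx1 reached 19.2 ± 4.26 CPM in mutator with no counts in WT, which makes it at least 801-fold higher, and Tbx4 reached 29.0 ± 1.1 CPM against 1 count in WT, a ratio of 3600 (exact 95% interval 646 to 142000). The kidney regulator Pax2 was 20.01 ± 0.812 CPM in mutator with no counts in WT. The protocadherin gene Pcdh7 was at least 976-fold higher and Tfpi, a coagulation inhibitor, was 39.3 ± 1.04 CPM in mutator against 0.033 ± 0.029 CPM in WT. In the other direction, Tbx5, a transcription factor of forelimb and heart, was 27.3 ± 0.543 CPM in WT with no counts in mutator, at least 1890-fold lower. Tcfap2b, encoding the transcription factor AP-2 beta, was 58.2 ± 1.44 CPM in WT with no counts in mutator, at least 4020-fold lower. Col10a1, the collagen of hypertrophic cartilage, was 321-fold lower (72.8 ± 2.44 against 0.225 ± 0.044 CPM), Slit2, an axon guidance ligand, 252-fold lower, the adhesion gene Flrt3 85.1-fold lower and Krt18, a keratin of simple epithelia, 80.3-fold lower.

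RNAs of the proteasome core and regulator were lower in mutator for most subunits, by modest amounts. In the 20S core, 12 of 14 genes fell, 1 rose (Psma4, log2 fold change 0.18) and Psma7 did not pass (-0.06); the median was -0.28. Psma5 (GRCm38 chromosome 3, 108256926 to 108279952) fell 2.19-fold, from 251 ± 11.2 CPM (SD, n = 4) to 115 ± 2.62 CPM (SD, n = 5), with a log2 fold change of -1.13 ± 0.029 (SE, adjusted p = 1.22e-16). Psmb4 (chromosome 3, 94884324 to 94886958) fell 2.1-fold, from 302.8 ± 13.6 to 144 ± 3.28 CPM, and Psmb2 (chromosome 4, 126677637 to 126709715) fell 1.55-fold. Psmb5, which carries the chymotrypsin-like site, fell 1.21-fold, from 169 ± 6.2 to 140 ± 7.13 CPM (log2 fold change -0.27 ± 0.035, adjusted p = 1e-06); relative to the median of its chromosome its log2 fold change was -0.03 and did not pass. In the 19S regulator, 15 of 19 genes fell, Psmc3 (0.16) and Psmd14 (0.09) rose, and Adrm1 (0.06) and Shfm1 did not pass; the median was -0.24. Psmd4, a ubiquitin receptor on chromosome 3, fell 1.76-fold, Psmd6 1.44-fold and Psmd8 1.36-fold. Psmd11, a subunit tied to proteasome assembly in stem cells, had a log2 fold change of -0.16 ± 0.024, and did not pass after the GC and length correction (-0.02). Camera gave an adjusted p of 0.00708 for either list; with an estimated correlation the adjusted p was 0.476 for the core and 0.43 for the regulator.

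**Figure D1:**
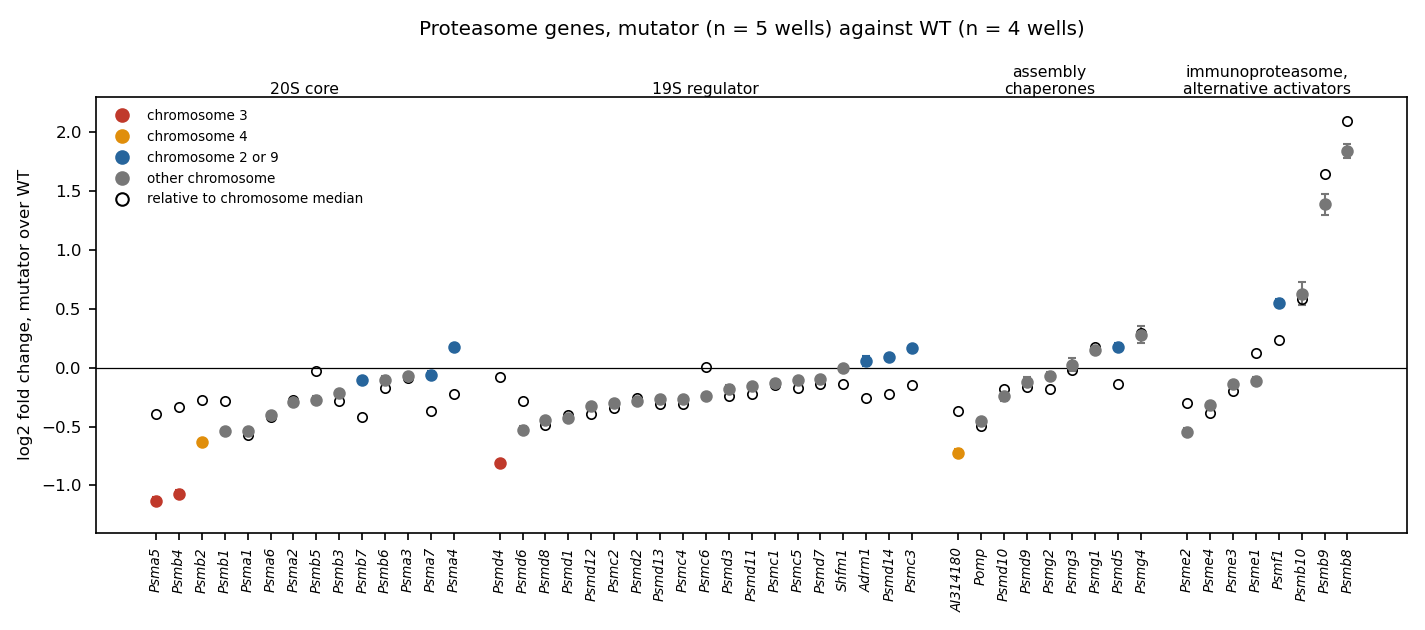
Log2 fold change of mutator over WT for the 50 proteasome genes tested, with filled points coloured by chromosome and bars for the SE, and open points for the same gene relative to the median of its chromosome. Psma5 (-1.13), Psmb4 (-1.07) and Psmd4 (-0.81), on chromosome 3, lie lowest, and Psmb8 (1.84) and Psmb9 (1.39) highest.

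Subunits encoded on chromosome 3 showed the largest falls, and genes of that chromosome were lower as a block. The median log2 fold change of its 611 tested genes was -0.73, and 80.9% of them were lower, against 37.7% on all other chromosomes. The medians were -0.36 on chromosome 4, -0.26 on chromosome 17, -0.24 on chromosome 14 and -0.21 on chromosome 10, and they were 0.40 on chromosome 9 and 0.31 on chromosome 2 (permutation p = 0.0001 for each of these 7 chromosomes, the smallest that 10000 permutations can give). Chromosomes 6 (0.135, permutation p = 0.0006) and 18 (0.113, permutation p = 0.0046) also deviated. All 16 windows of 10 Mb on chromosome 3 had a negative median, from -1.02 to -0.60. Windows were less even on chromosome 17, from -0.627 to -0.018, and on chromosome 10, from -0.449 to -0.047. A single median therefore does not describe every part of those chromosomes. Psmb8 and Psmb9 lie in the chromosome 17 window at -0.018. Relative to the chromosome medians, 13 of 14 core genes and 18 of 19 regulator genes were lower and none was higher, with medians of -0.28 and -0.24 (camera adjusted p = 0.000684 and 0.000232; with an estimated correlation adjusted p = 0.327 and 0.238). On that scale Psma5 was at -0.40, Psmb4 at -0.34 and Psmd4 at -0.08, and Psma4, Psmc3 and Psmd14, on chromosomes 9 and 2, turned to -0.22, -0.15 and -0.22.

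**Figure D2:**
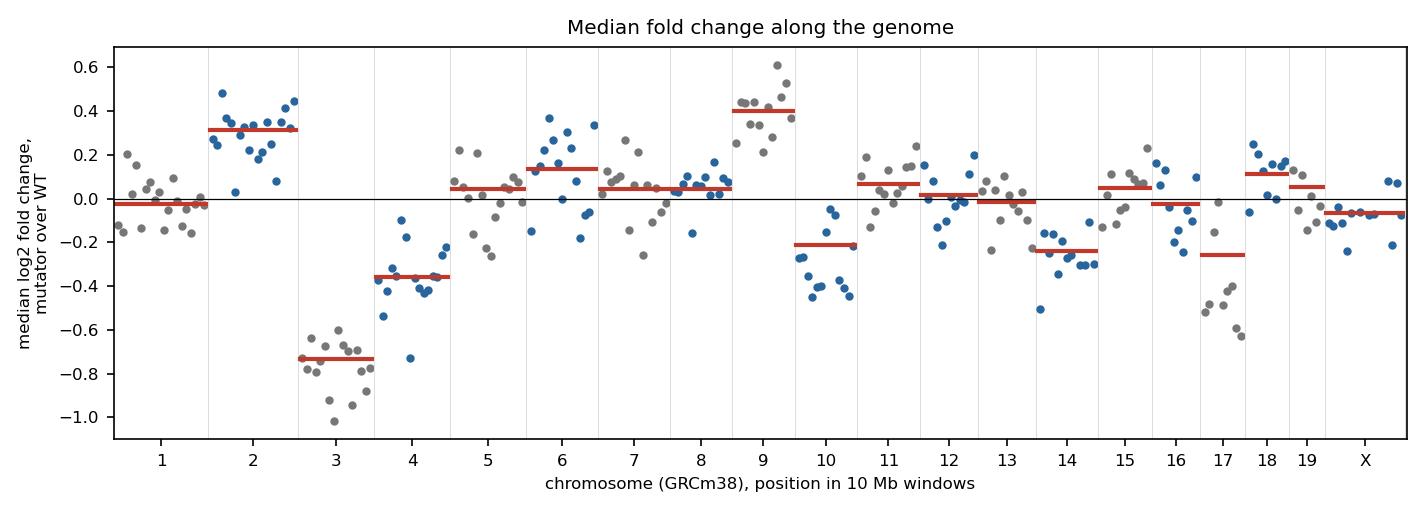
Median log2 fold change of mutator over WT in windows of 10 Mb with at least 5 tested genes along the GRCm38 chromosomes (points), and over each whole chromosome (red lines). Chromosome 3 lies at -0.73, chromosome 9 at 0.40 and chromosome 2 at 0.31.

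Assembly chaperones and alternative subunits moved both ways. Of 9 assembly genes tested, 4 fell and 3 rose, with Psmg2 (-0.07) and Psmg3 (0.03) not past the threshold (median -0.07, camera adjusted p = 0.538). AI314180, the older symbol of the proteasome adaptor gene Ecpas, fell 1.65-fold, and Pomp, the maturation factor of the core, fell 1.37-fold. The 19S chaperone Psmd10 fell from 42.7 ± 1.54 to 36.1 ± 1.46 CPM (log2 fold change -0.24 ± 0.036, adjusted p = 7.86e-06), and was at -0.06 and did not pass after the GC and length correction. Psmd9, another such chaperone, fell 1.09-fold (log2 fold change -0.12, adjusted p = 0.0104) and did not pass under upper quartile scaling. Psmd5 rose from 107 ± 3.75 to 121 ± 4.5 CPM (log2 fold change 0.18 ± 0.031), but was at -0.14 relative to its chromosome median. Psmg4 (0.28) and Psmg1 (0.15) also rose. Among immunoproteasome subunits and alternative activators, 4 of 8 rose and 4 fell (median 0.22, camera adjusted p = 0.781). The catalytic immunoproteasome subunits Psmb8, Psmb9 and Psmb10 rose 3.58-fold, 2.62-fold and 1.55-fold; Psmb8 went from 8.07 ± 0.367 to 28.9 ± 2.18 CPM. Psmf1 (0.55) rose, and Psme1 (-0.12), Psme2 (-0.54), Psme3 (-0.13) and Psme4 (-0.32) fell. Over these 4 lists, 10 of 50 genes were higher and 35 lower, and the counts were 10 and 35 adjusted over the list alone. Only 4 of them, Psma5, Psmb4, Psmb8 and Psmb9, changed by at least 2-fold, and their median absolute log2 fold change, 0.27, was below that of all genes, 0.35.

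Of 16 genes for proteasome transcription and ubiquitin supply, 12 fell and 2 rose (median -0.14, camera adjusted p = 0.0907). Nfe2l1, the transcription factor that drives proteasome genes, was 340.8 ± 5.56 CPM in WT and 362 ± 4.43 CPM in mutator (log2 fold change 0.09 ± 0.021), and did not pass relative to its chromosome median (0.02). After the GC and length correction it was past the threshold in the other direction (-0.05, edgeR adjusted p = 0.0263). The same held with chromosome medians removed as well (-0.123, adjusted p = 3.08e-05), so its direction depended on the correction. Nfe2l2, encoding NRF2, rose 1.43-fold. Vcp, the unfoldase that delivers substrates, fell 1.58-fold, from 1038 ± 15.6 to 655 ± 12.7 CPM; it lies on chromosome 4. Zfand2a fell 1.36-fold. Ubb did not pass (0.03), and reads of the polyubiquitin genes may be split between near-identical repeats.

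Genes of mitochondrial function moved both ways, with more members lower than higher. Among nuclear subunits of complex I, 18 of 36 were lower and 8 higher (median -0.07, camera adjusted p = 0.123), and among those of complexes II to V, 22 of 39 were lower and 10 higher (median -0.09, adjusted p = 0.171). Ndufv2 fell 1.71-fold, Ndufb5 1.68-fold, Ndufs5 1.65-fold, Atp5f1 1.93-fold and Uqcrh 1.91-fold, while Uqcrq rose 1.7-fold. Ndufb5 and Atp5f1 lie on chromosome 3, and Ndufs5 and Uqcrh on chromosome 4; relative to its chromosome median Ndufb5 was at -0.01 and did not pass. Of 58 mitochondrial ribosome genes, 27 were lower and 17 higher (median -0.08, adjusted p = 0.149), led by Mrpl9 (2.17-fold lower), Mrps21 (1.87-fold) and Mrpl24 (1.67-fold), which all lie on chromosome 3; Mrpl24 did not pass relative to its chromosome median. For mitochondrial DNA maintenance and transcription, 13 of 30 were lower and 10 higher (median -0.05, adjusted p = 0.515). Tfam, which packages mitochondrial DNA, fell 1.61-fold from 87.2 ± 3.7 to 54.2 ± 1.59 CPM, Tfb1m 1.72-fold and Lrpprc 1.6-fold. Mitochondrial chaperones and proteases gave 9 of 16 lower and 6 higher (median -0.16, adjusted p = 0.437), with Trap1 1.39-fold higher, Lonp1 1.31-fold lower and Oma1 1.36-fold lower, the last not past the threshold relative to its chromosome median. In the tricarboxylic acid cycle, 13 of 21 were lower and 7 higher (median -0.11, adjusted p = 0.336), with Pdhb 1.67-fold, Cs 1.32-fold and Sucla2 1.28-fold lower, the last not past the threshold with chromosome medians and the GC and length trend both removed (-0.01). Of 13 proteins encoded by mitochondrial DNA, 2 were found by name: Cytb fell 1.65-fold (5135 ± 815 to 3115 ± 131 CPM) and mt-Nd4 1.35-fold. Nnt was at 105 ± 1.2 CPM in WT and 80.2 ± 1.8 CPM in mutator.

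Targets of ATF4, the transcription factor of the integrated stress and amino acid response, rose as a group. Of 43 genes, 36 rose and 5 fell (Slc7a3, Atf3, Ppp1r15a, Nupr1 and Sars), with Phgdh and Mars not past the threshold (median 0.53, camera adjusted p = 5.48e-06; adjusted p = 0.35 with an estimated correlation). Atf4 itself rose 1.44-fold, from 280.1 ± 6.68 to 404 ± 7.48 CPM (log2 fold change 0.53 ± 0.023, adjusted p = 2.74e-13). The cystine transporter Slc7a11, which is also on the list of NRF2 targets, rose 5.93-fold, from 7.83 ± 0.288 to 46.6 ± 2.57 CPM, although it lies on chromosome 3. The hormone gene Stc2 rose 5.74-fold and Vldlr 5.34-fold. Atf3 (-0.52) and Ppp1r15a (-0.36), both stress-induced genes, were among those that fell. In aspartate and glutamine metabolism, 15 of 25 were higher and 8 lower (median 0.17, mean -0.06, camera adjusted p = 0.336), with the aspartate and glutamate transporter Slc1a3 13.9-fold lower, the glutamine synthetase gene Glul 2.62-fold higher and Ass1 2.1-fold higher.

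Glycolysis genes rose and cholesterol synthesis genes fell. Of 20 glycolysis genes, 16 rose, Hk1, Aldoc and Slc16a1 fell and Eno1 did not pass (median 0.51, camera adjusted p = 0.00477; adjusted p = 0.419 with an estimated correlation). The lactate exporter Slc16a3 rose 184-fold, from 1.37 ± 0.229 to 254 ± 13.8 CPM, whereas the other monocarboxylate transporter of the list, Slc16a1 on chromosome 3, fell 3.04-fold; Pdk1, which inhibits pyruvate dehydrogenase, rose 4.1-fold. Of 23 cholesterol genes, 21 fell (median -0.65, camera adjusted p = 1.83e-05; adjusted p = 0.35 with an estimated correlation), led by Fdps (3.23-fold) and Pmvk (2.84-fold), both on chromosome 3. Tm7sf2 did not pass (-0.04).

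**Figure D3:**
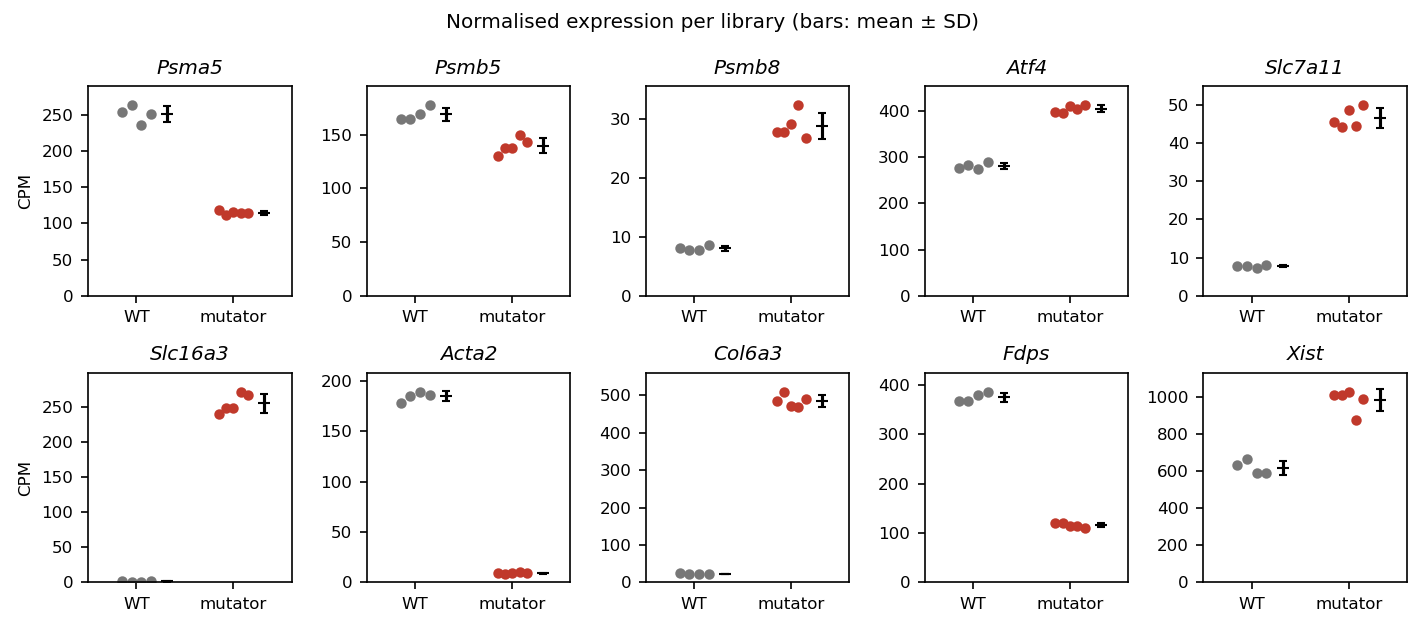
CPM per library for 10 named genes in WT (grey, n = 4) and mutator (red, n = 5), with mean and SD beside the points on axes that start at 0. Slc16a3 went from 1.37 to 254 CPM and Acta2 from 185 to 9.16 CPM, while Psmb5 went from 169 to 140 CPM.

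Matrix genes rose and contractile genes fell. Of 28 collagen and matrix genes, 21 rose and 7 fell (median 1.33, camera adjusted p = 0.00493; adjusted p = 0.476 with an estimated correlation). Col6a3 rose 21.2-fold, from 22.9 ± 0.845 to 484.8 ± 16.6 CPM, Thbs2 20.3-fold and Col6a2 15.8-fold. Of 14 myofibroblast and smooth muscle genes, 10 fell, Tagln, Smtn and Flna rose and Des did not pass (median -0.53, camera adjusted p = 0.0451; adjusted p = 0.35 with an estimated correlation). This call is weak: the adjusted p was 0.151 under the stricter filter. It was 0.0637, 0.0688, 0.0705 and 0.0533 without WT replicate 1, 2, 3 and 4, and 0.0548, 0.0508 and 0.0577 without mutator replicate 1, 2 and 5. The smooth muscle actin Acta2 fell 20.1-fold, from 185 ± 4.99 to 9.16 ± 0.444 CPM, and Cnn1 2.72-fold, while Tagln rose 1.71-fold; reads of actin genes with near-identical coding sequence may be split between them.

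The p53 target and senescence list fell, with 16 of 22 genes lower, 4 higher, among them Gdf15, Sesn2 and Aen, and Bbc3 and Cdkn2a not past the threshold (median -0.28, camera adjusted p = 0.0286; adjusted p = 0.419 with an estimated correlation, and 0.052 relative to chromosome medians). Pmaip1, a pro-apoptotic target, fell 4.37-fold and Trp53inp1 2.57-fold, while Gdf15, also an ATF4 target, rose 3.46-fold. Of 17 secreted factors associated with senescence, 13 were higher (median 1.00, adjusted p = 0.117), with Cxcl5 51.6-fold, Hgf 30.8-fold and Cxcl2 23.8-fold higher, and Plau, Csf1 and Tnfrsf11b lower. Cxcl5 varied between the mutator libraries, from 50.2 to 168 CPM, and was highest in replicates 4 and 5, as was Cxcl2. Of 32 proliferation genes, 20 were lower and 8 higher (median -0.15, adjusted p = 0.0766), with Cdc20, Cenpe and Ccna2 1.94-fold, 1.88-fold and 1.87-fold lower; they lie on chromosomes 4, 3 and 3. NRF2 targets and antioxidant enzymes gave 13 of 26 higher and 11 lower (median 0.01, adjusted p = 0.781), with Gsta4 18.2-fold higher and Gclm, on chromosome 3, 1.9-fold lower. Slc7a11, also on the ATF4 list, was 5.93-fold higher. The type I interferon response gave 16 of 28 lower and 7 higher (median -0.29, adjusted p = 0.153), with Zbp1 5.13-fold and Ccl5 2.13-fold higher and Oasl1 2.12-fold lower. The unfolded protein and heat shock list gave 19 of 29 lower and 8 higher (median -0.21, adjusted p = 0.108), with Hspb1 2.65-fold and Cryab 2.12-fold higher and Hsph1 1.93-fold lower. Autophagy and lysosome genes gave 18 of 34 higher and 10 lower (median 0.13, adjusted p = 0.153), with Gaa 2.58-fold, Mitf 2.42-fold and Ctsz 2.32-fold higher.

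Markers of position and cell identity also differed. Of 24 Hox genes tested, 10 were higher and 9 lower (median 0.06, also 0.06 with the 4 genes that have no WT counts at their bound; camera adjusted p = 0.538). Hoxb6, Hoxb3 and Hoxb4 had no counts in WT and were at least 180-fold, 171-fold and 106-fold higher in mutator; Hoxb3 and Hoxb4 overlap in the annotation. Of 15 imprinted genes, 10 were higher and 5 lower (median 1.05, also 1.05 with the 4 genes that have no WT counts at their bound; adjusted p = 0.149). Rian, Ndn and Dlk1 had no counts in WT and were at least 203-fold, 124-fold and 108-fold higher. Xist, the RNA of the inactive X chromosome, was 618 ± 36.9 CPM in WT and 981 ± 60.9 CPM in mutator, 1.59-fold higher. The 4 Y-linked genes together had 1 count in the 9 libraries, and Ddx3y had none, which allows at most 0.0606 to 0.114 CPM per library.

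Markers of other cell types moved in different directions, with no list past the threshold in camera, whose adjusted p is given for each. For macrophages, 3 of 12 listed genes were expressed enough to test and all were higher (Csf1r, Cd14 and Cd68; Cd14 12.2 ± 1.05 CPM in mutator; adjusted p = 0.117). For endothelium, Egfl7 and Erg were higher and Kdr did not pass (adjusted p = 0.501); Egfl7 did not pass with chromosome medians and the GC and length trend both removed (0.10). For epithelium, Krt19 was 5.81-fold higher, Krt18 and Cdh1 were lower and Cldn7 did not pass (adjusted p = 0.515). The skeletal muscle genes Acta1 and Tnnt2 were 12.5-fold and 2.57-fold lower, 2 genes being too few for a list test. Among neural genes, Nes was 4.38-fold higher, Sox2 4.1-fold lower and Mtap2 3.51-fold lower (4 higher, 2 lower, adjusted p = 0.67). Among adipocyte genes, Fabp4 was 3.16-fold lower, Cebpa and Lpl were higher and Pparg did not pass (adjusted p = 0.606). Among cartilage and bone genes, Col2a1 was 5.82-fold higher, Runx2 2.03-fold lower, Col10a1 and Sox9 lower, and Acan and Comp did not pass (adjusted p = 0.336).

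**Figure D4:**
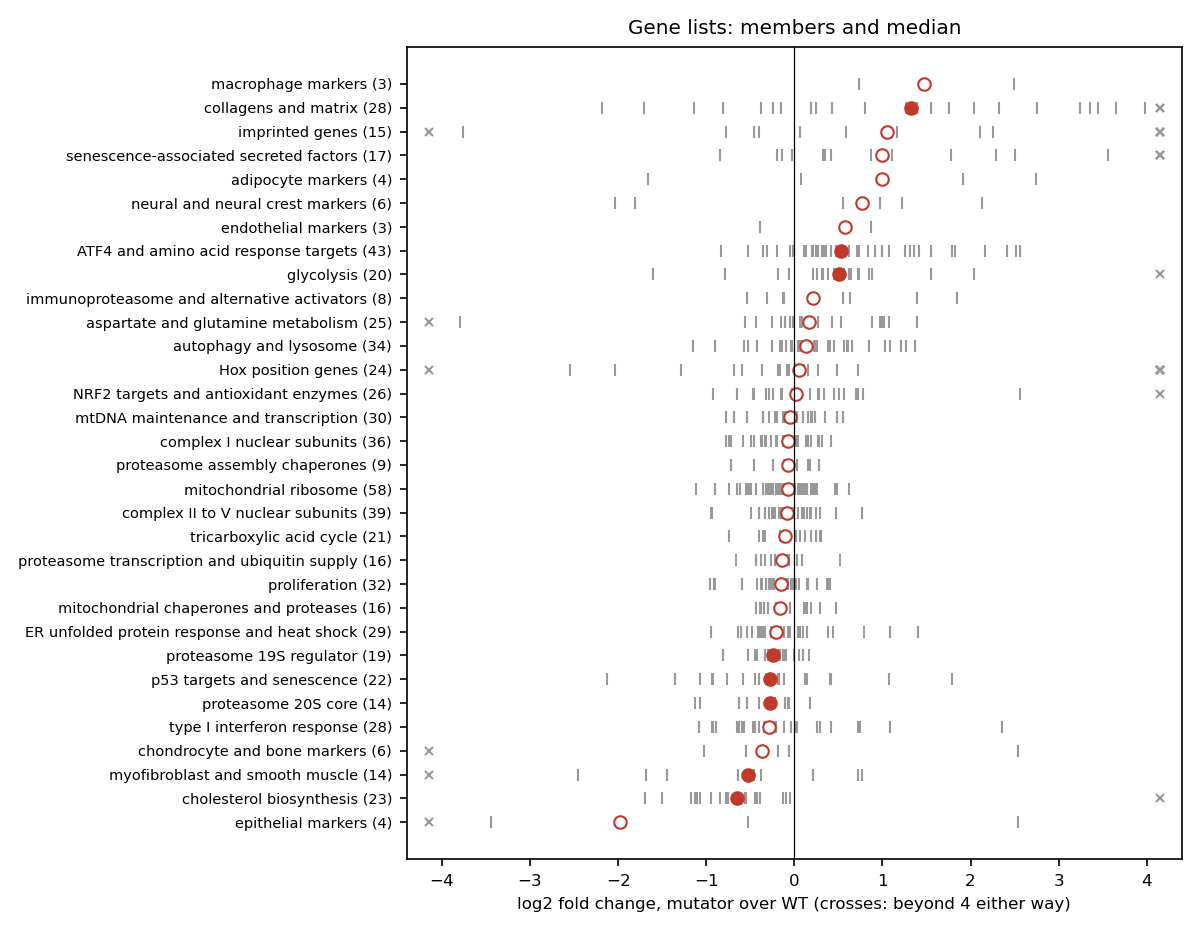
Log2 fold change of the tested members of 32 gene lists (ticks, number of tested genes in brackets) and their medians (circles, filled where the camera adjusted p was under 0.05). The collagen and matrix list has the highest filled median (1.33) and cholesterol synthesis the lowest (-0.65).

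In all, 8 of the 32 lists tested passed camera, 3 upward and 5 downward, while 31 passed fry. With limma's estimated correlation none passed, and 3 had an unadjusted p under 0.05: ATF4 targets (0.0211), the myofibroblast list (0.0309) and cholesterol synthesis (0.0328). Over all alternatives with camera, the adjusted p ranged from 1.35e-08 to 0.35 for ATF4 targets, from 0.000352 to 0.419 for glycolysis, from 0.00932 to 0.419 for p53 targets, from 0.00114 to 0.476 for matrix genes, from 0.0213 to 0.35 for the myofibroblast list and from 3.12e-07 to 0.35 for cholesterol synthesis, each highest with the estimated correlation. Adjusted over the list alone, the counts of higher and lower genes were those given above except for 17 lower genes in complex I, 9 lower in aspartate and glutamine metabolism and 5 higher among p53 targets.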

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

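Among 225 groups of values, those of the named genes and of the library measures in either line, 5 held a library far from the others of its group by Dixon's ratio (gap to the nearest library over the range of the group). Chance gives about 1 in 20, or 11.2 here. Nfe2l2 was at 145 CPM in mutator replicate 5 and 139.0 to 139.5 CPM in the other mutator libraries (ratio 0.919). Atp5f1 was at 313 CPM in WT replicate 3 and 346.7 to 352.7 CPM in the other WT libraries (ratio 0.848). Pcdh7 was at 21.3 CPM in mutator replicate 2 against 23.9 to 24.8 CPM (ratio 0.754). Col6a2 was at 335 CPM in mutator replicate 4 against 302 to 310.2 CPM (ratio 0.748), and Xist was at 875 CPM in mutator replicate 4 against 987.5 to 1027 CPM (ratio 0.74). In each case the outlying library stayed on the same side of the other line as its fellows.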

How the results depend on the processing

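The chromosome-centred and GC and length corrected settings, both together, and the library sizes without rows named by accession were chosen after the data were seen. Over all other settings that give a count and the 9 in which 1 library was left out, the counts of genes higher and lower in mutator stayed within 1.5 times those reported, and leaving out any library gave 5281 to 5365 higher and 5100 to 5234 lower. Proteasome genes ranged from 7 to 12 higher and 30 to 40 lower over the alternatives. With the replicate block, 5357 genes were higher and 5124 lower, 1510 and 862 by at least 2-fold, 10 and 35 among proteasome genes, and 8 lists passed; the adjusted p was 0.00725 for the core, 0.0136 for the regulator, 0.499 for the assembly chaperones and 0.74 for the immunoproteasome list. Same-numbered libraries of the lines did not deviate together (correlations -0.08, 0.027, -0.034 and 0.004 across genes). These values give no sign of pairing by number but cannot exclude it, and the labels state none.

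Genes changed by at least 2-fold numbered 610 higher and 321 lower under the stricter filter, and 1372 were lower with no filter, as fewer and more low-count genes were tested. Under glmTreat, which asks for a fold beyond 1.5 rather than a fitted fold of 2, 1461 were lower. With limma's estimated correlation 0 lists passed (3 at an unadjusted p under 0.05), with 0 also after chromosome centring (6 unadjusted); the core then had an adjusted p of 0.476 and 0.327 and the regulator 0.43 and 0.238. With fry 31 lists passed, among them the assembly chaperones (7.41e-06) and the immunoproteasome list (0.000105), and the neural list turned downward (0.0489). Over the alternatives with camera, the adjusted p of the core ranged from 0.000684 to 0.476 and that of the regulator from 0.000232 to 0.43; fry, a test against no change, gave 1.57e-07 and 6.18e-08. The direction of 5 named genes turned. Psmd5 went to -0.136 when centred on its chromosome and to -0.097 with both corrections, past the threshold each time. Nfe2l1 went to -0.053 with the GC and length correction and -0.123 with both, also past the threshold each time. Polg went to -0.037 with the GC and length correction, not past the threshold, and to -0.086 with both, past it. Ndufb5 went to 0.013 and Mrpl24 to 0.058 with both, neither past the threshold. The cause was not tested beyond what each correction removes. Upper quartile scaling moved the median of all genes by 0.044 and no scaling moved it further. The planned library sizes without mitochondrial genes left out 1 row and so tested little. Of 113 named genes with a test, 12 changed direction or side of the threshold in any setting. Depth limits what can be said of genes with no counts to the floor of 3 counts over a group.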

Other observations

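Of the tests below, those of the windows along chromosome 3, of the spread among the 33 proteasome genes, of chromosome medians, of GC content and length and of the make-up of the splits were chosen after the data were seen. The test that removes chromosome medians and the GC and length trend together was added only once the GC and length test alone had left the proteasome median inside the range of random lists. Genes of the HoxB and imprinted families beyond those named above were also chosen after their values were seen. Hoxb5 had no counts in WT and was at least 81.1-fold higher in mutator, Hoxb8 had 2 counts in WT and a ratio of 133 (exact 95% interval 36.7 to 1100), and the imprinted RNA Meg3 was at least 93.9-fold higher. Within the mutator line, cytokine genes varied between wells that were plated alike: Ccl2 ran from 36.8 to 156 CPM (4.25-fold), Cxcl1 from 5.95 to 31.2 CPM (5.24-fold) and Cxcl5 from 50.2 to 168 CPM (3.35-fold). In WT, Ccl2 ran from 40.9 to 46.2 CPM (1.13-fold) and Cxcl1 from 16.3 to 20.7 CPM (1.27-fold). Lif (13.45 to 40.2 CPM) and Tnfaip3 (24.6 to 51.8 CPM), known targets of NF-kB, also varied between mutator wells, and were at 76.3 to 79.4 and 108.1 to 111.2 CPM in WT. These 5 genes rose in order from mutator replicate 1 to 4, and all were higher in replicates 4 and 5 than in the other mutator libraries. Ccl2 was at 36.8, 48.6, 77.8, 146 and 156 CPM in mutator replicates 1 to 5. The second principal component (1.2% of the variance) rose in the same order, from -11.43 in mutator replicate 1 to 8.62 in replicate 5. The WT libraries also spread along it, from -8.63 in replicate 2 to 10.94 in replicate 3, although their Ccl2 and Cxcl1 varied little. The component is thus not particular to the cytokine order. The cause of the order among the mutator replicates was not tested.

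Relative to chromosome medians, 12 lists passed camera, 7 of them among the 8 reported. The lists that joined were complexes II to V (median -0.15, adjusted p = 0.00664), the tricarboxylic acid cycle (-0.12, 0.0248), proliferation (-0.20, 0.000352), unfolded protein and heat shock (-0.21, 0.0235), all lower, and senescence-associated secreted factors (1.04, 0.0162), higher. ATF4 targets then stood at 39 higher and 4 lower of 43. With an estimated correlation none passed (6 at an unadjusted p under 0.05).

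The block of chromosome 3 genes was weighed first. A GC content or transcript length bias was not the whole cause, since the median moved only from -0.734 to -0.696 when that trend was removed, and the effect of a few genes or of 1 segment was excluded by the windows, of which all 16 lay low, between -1.018 and -0.602. The genes lower by at least 2-fold were also concentrated there (143 of 611 against 650 on other chromosomes, Fisher's exact test p = 1.02e-45 over genes, which are not independent replicates). A candidate explanation is that the lines carry different numbers of copies of chromosome 3: the shift was of similar size in genes of low, middle and high expression (-0.58, -0.76 and -0.77, a spread of 0.191), as such a difference predicts. Any other cause that acts along the whole chromosome could give the same, so the similar size does not single out copy number. The size of the shift was not set against a copy ratio, and the shifts on other chromosomes were not tested in this way. DNA was not measured here, so a copy difference stays a hypothesis, and a difference that arose in culture cannot be assigned to the genotype.

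The fall of the 33 core and regulator genes was weighed next. Chromosome-wide shifts did not remove it: relative to chromosome medians the median was -0.272, against -0.268 before, and lay at percentile 0.03 of matched random lists (central 95% from -0.191 to 0.042). Random lists leave out the correlation among these genes. With a correlation estimated from the wells, the centred lists did not pass camera (adjusted p = 0.327 for the core and 0.238 for the regulator). That estimate reflects technical deviations between wells within each line, and the correlation between independent lines was not measured. For GC content and length the tests were mixed. With that trend removed the median was -0.209, at percentile 4.65 and inside the central 95% of random lists (from -0.225), so the trend may carry part of the fall. With chromosome medians removed as well it was -0.242, at percentile 0.36 and outside them (from -0.2). As this second test was added in the light of the first, the GC and length trend stays open for part of the fall. A lower expression of the subunits with the mutator genotype remains open and untested, since genotype and line coincide.

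The differences among those subunits were weighed last. The SD of their log2 fold changes fell from 0.307 to 0.132 when each gene was taken relative to its chromosome median, and 32 of the 33 then lay below 0 in place of 28. When the chromosome medians were reassigned to chromosomes at random 10000 times, the SD was 0.377 in the median and never below 0.161 (permutation p = 0.0001, the smallest these can give). A hypothesis in line with this is that much of the contrast between strongly and weakly lowered subunits, such as Psma5 and Psmb4 against Psma4, reflects where the genes lie, over a more even fall of about the same median.

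Of the 126 splits of the 9 libraries into 4 and 5, 100 were drawn, the real one included. Only the real split reached its count of genes (10665 against 7521 in the highest other split). The same held for genes changed by at least 2-fold (2380 against 1183) and for proteasome genes (45 against 37). The splits only reassign wells between 2 lines that differ in most genes, so the real split had to rank high. With 1 line per genotype, they cannot say whether chance differences between lines give as many. For the number of lists past camera, 19 splits gave as many as the 8 of the real one and the highest other gave 14, so the share of splits alone does not exclude chance for it. The other splits that reached 8 lists all had at least 3 libraries of 1 line on the side of 4, and so still held part of the contrast between the lines: 9 of 14 drawn with 3 WT libraries there, 7 of 31 with 3 mutator libraries and 2 of 5 with 4 mutator libraries. Of the 49 with 2 libraries of each line there, 0 did, and the highest gave 6. The drawn splits with 3 libraries of 1 line or 2 of each on that side called 0 genes. Yet up to 14 lists passed with 3 WT libraries there and up to 13 with 3 mutator libraries. Camera at the preset correlation thus passed lists where no single gene passed. The splits with 4 mutator libraries on that side, which called 6305 to 7521 genes, point to the same structure of the samples.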
